A study of Arabidopsis thaliana with 12 samples.

How the data were processed

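Total RNA of seedling roots was depleted of ribosomal RNA and sequenced, per the labels' protocols. The 12 samples were assigned to 4 groups of 3 (WT control, WT paraquat, trm4b-1 control and trm4b-1 paraquat) from their labels. The submitters' processing notes name Trimmomatic, TopHat, limma and the genome build TAIR10, without versions. How reads were counted, whether strand was used, the normalization and any filter on low values are not given in the sources used here.

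The authors deposited 5 tables of comparisons, for 2 genotype contrasts, 2 paraquat contrasts and the interaction. Each deposited table gives, per the file headers, a log fold change (taken as log2 from limma's convention, since the header names no base), a p-value, an adjusted p-value and a Storey q-value for every gene listed, with exon coordinates. All listed genes had an adjusted p-value under 0.1 in the deposited tables. The tables hold no values per sample, so the depth per sample and the reads behind each gene are unknown, and low genes could not be set apart in general. The part of the naming rule that asks for mean expression could not be applied for the same reason. AT1G24485, AT1G80250 and AT4G37483 changed by -3.087, -3.357 and -2.260 with paraquat in WT. Between the genotypes under control conditions they had -3.359, -3.629 and -2.532, lower by the same amount in each gene. Values at a floor in the WT paraquat and trm4b-1 control groups would give this, so these genes are uncertain.

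The number of genes tested was recovered from adjusted p x rank / raw p and was 33602. No filter on low values is stated, so this number may include genes that were hardly expressed. Shares of tested genes and numbers for independent lists would then be too low. Overlaps and over-representation against all tested genes would look too strong. The deposited interaction equalled the difference of both paraquat contrasts in the 96 genes listed in all 3 tables, and that of both genotype contrasts in the 11 genes listed in all 3 of those, to within rounding. This fixes the orientation of the tables relative to each other, as trm4b-1 minus WT and paraquat minus control. The variance of the interaction must equal the sum of the variances of the contrasts it is made of, and solving this for the 96 genes gave 15.3 total degrees of freedom, of which 8 are residual. Each standard error is the deposited log2 fold change divided by the t value that the deposited p implies at these degrees of freedom. Contrasts that were not listed were rebuilt from listed ones where possible and are named as rebuilt where they are used. The recovery was tested on simulated data of 33602 genes with 4 groups of 3. For the simulated paraquat comparison of WT, 80.0% of 100 genes changed by a log2 value of 1 and 99.0% of 100 genes changed by 2 were called. The simulated variances were drawn from genes listed in that deposited comparison. Genes too variable to be listed are therefore left out, and these shares may be too high for genes in general.

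Genes were counted as changed at an adjusted p under 0.05. Before the data were examined, 18 lists with 349 gene entries and 4 lists defined by annotation text or genome were fixed, 22 in all, together with the comparisons, the tests and the rule for naming genes. The text pattern of the ribosomal protein list (329 genes) also takes in some nuclear genes for organelle ribosomes. The rule names TRM4B, the 8 largest positive and 8 largest negative fold changes, the 3 lowest adjusted p values per direction, and up to 4 changed members of each list with at least 3, and the text prints from the top of each ranking. LRX1 and CYP82C2 are named by the rule in the paraquat comparison and recur in the overlaps. Direction was tested with a two-sided Fisher's exact test of members against all other changed genes, and over-representation with a one-sided one in which every member counted as tested, each adjusted over the lists of a comparison by the Benjamini-Hochberg method. Organelle genome lists entered the direction test alone. Counts adjusted over the list alone treat members that are not listed as having p of 1, so they are lower bounds. Shared controls were simulated with unchanged groups and independent genes 100 times.

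Gene names came from the annotation of assembly TAIR10.1, which matched 8492 of the 8607 genes listed in any table (98.7%), and it served only for names and for which genes neighbour each other. Coordinates are those of the deposited tables. Close paralogs, overlapping genes and antisense pairs cannot be told apart from these values. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

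Alternatives planned before the data were examined and run were an adjusted p under 0.01, a log2 change of at least 1, Holm adjustment, leaving out organelle genes, the interaction rebuilt from the paraquat contrasts, other backgrounds, and values rebuilt from other contrasts. An adjusted p under 0.1, the Storey q and a comparison with the other paraquat table were added after the data were seen. Of 17 tests of explanations, 13 were written after the values they bear on had been seen, and some replaced earlier forms, which the closing section gives with their values. Adjusted p values printed for genes are those of limma in the authors' deposited tables.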

Results

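RNA was sequenced from roots of Arabidopsis thaliana seedlings harvested 6 days after germination. Wild-type plants of accession Col-0 (WT) and plants labelled trm4b-1 were grown on medium without paraquat (control) or with 0.01 uM paraquat, a herbicide that makes cells form superoxide. TRM4B is an RNA cytosine methyltransferase, an enzyme that forms 5-methylcytosine in RNA. The 12 samples formed 4 groups of 3 replicates, which the series' design text calls biological. The files used here hold the authors' tables of 5 comparisons and no values per sample, so the depth of each library and the spread between single replicates are unknown. Each table lists only genes with an adjusted p under 0.1. Below, "changed" means an adjusted p under 0.05 in the authors' deposited table (limma, per the submitters' processing notes). Fold changes are read as log2 values from limma's convention, since the tables name no base, and each ± is a standard error recovered from the deposited fold change and p.

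TRM4B itself (AT2G22400) was examined first, because it checks the genotype labels. The gene lies on chromosome 2 of TAIR10 from 9504659 to 9508875 on the minus strand, in 15 exons. TRM4B RNA was higher, not lower, in the libraries labelled trm4b-1. Under control conditions the authors' deposited table gave a difference of 2.89 ± 0.08 (adjusted p = 5.64e-12), which is 7.43-fold. Under paraquat the authors' deposited table gave 3.90 ± 0.08 (adjusted p = 6.52e-14), which is 14.9-fold. With paraquat TRM4B rose by 0.99 ± 0.08 in the libraries labelled trm4b-1 (adjusted p = 4.07e-07 in the authors' deposited table). In WT it was not listed, and the value rebuilt from the authors' deposited tables was -0.02 ± 0.08. The neighbouring gene SLO1 (AT2G22410, chromosome 2, 9509017 to 9511231, plus strand), which encodes a mitochondrial RNA editing factor, starts 141 bases from the annotated start of TRM4B and is transcribed away from it. SLO1 was also higher in the libraries labelled trm4b-1, by 2.24 ± 0.21 under control conditions and 2.03 ± 0.18 under paraquat in the authors' deposited table. Every direction given below for a genotype is that of libraries labelled trm4b-1, in which the RNA of the named gene was raised. It is not stated whether counting used strand, and a value per gene does not show whether a full-length transcript was made.

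**Figure D1:**
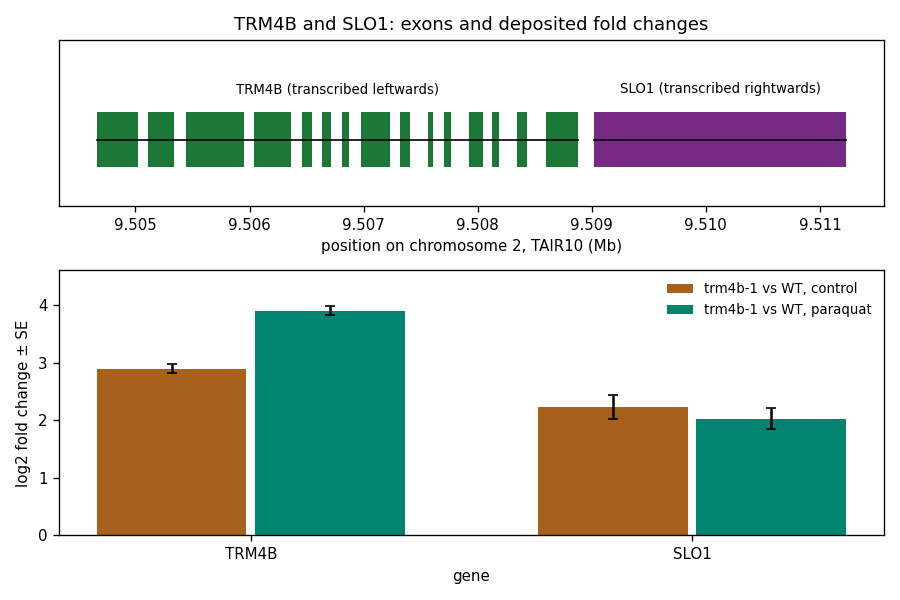
The upper panel maps the 15 exons of TRM4B and the single exon of SLO1 on chromosome 2 of TAIR10 (horizontal axis in Mb). The lower panel shows the log2 fold change of libraries labelled trm4b-1 over WT in the authors' deposited tables, with bars for the 2 growth conditions and error bars of 1 standard error, and both genes were higher in both conditions, TRM4B by 2.89 and 3.90.

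The first genotype comparison asked how roots labelled trm4b-1 differ from WT without stress. In all, 683 of 33602 tested genes changed (2.03%), 282 higher and 401 lower. Of 17 oxidative and mitochondrial stress markers, 5 rose and none fell, and at least 6 passed when adjusted over the list alone. NDB4, a mitochondrial NAD(P)H dehydrogenase, rose by 4.13 ± 0.36, UPOX, a marker gene of oxidative stress, by 3.23 ± 0.21 and AT12CYS-2 by 2.82 ± 0.39 in the authors' deposited table. Among the 22 genes of iron deficiency and storage, 5 rose, none fell and at least 5 passed when adjusted over the list alone. The ferric chelate reductase gene FRO2 rose by 1.48 ± 0.16, the iron deficiency regulator BHLH38 by 1.38 ± 0.29 and the iron transporter gene IRT1 by 1.34 ± 0.14 in the authors' deposited table. Among 15 root hair genes, 11 fell, none rose and at least 13 passed when adjusted over the list alone. The wall protein genes PRP1 and PRP3 changed by -2.00 ± 0.25 and -1.43 ± 0.20, and RHS19 by -1.26 ± 0.21 in the authors' deposited table. Photosynthesis genes, used as markers of shoot tissue, had 2 of 26 members lower and none higher, and at least 5 passed when adjusted over the list alone.

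Under control conditions AT1G58983, a ribosomal protein gene, had the largest rise in the authors' deposited table (7.33 ± 0.55), but it has near-identical copies that could share its reads, so its value is uncertain. AT5G53230, which encodes a protein of a domain family of unknown function, rose by 5.65 ± 0.44, AT4G05370 by 5.01 ± 0.63, AT4G05380 by 4.68 ± 0.42 and the transcription factor gene NAC085 by 4.56 ± 0.58 in the authors' deposited table. The largest falls were those of MRD1 (-7.79 ± 0.52) and AT5G63250 (-4.26 ± 0.73) in the authors' deposited table. After TRM4B, the lowest adjusted p values of rises belonged to ACC2, an acetyl-CoA carboxylase gene (2.24 ± 0.13, adjusted p = 3.14e-07), and WRKY25, a transcription factor gene (1.78 ± 0.11, adjusted p = 5.33e-07), in the authors' deposited table. Those of falls belonged to MRD1, AT1G33700 (-1.58 ± 0.11) and the sucrose transporter gene SWEET11 (-3.01 ± 0.27) in the authors' deposited table.

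The direction of list members was set against that of all other changed genes by a two-sided Fisher's exact test, adjusted over the lists of the comparison. The adjusted p was 0.0441 for each of 4 lists, namely the stress markers, iron genes, root hair genes and ribosomal proteins. Of the last, 5 of 329 rose, AT1G58983 among them. With an adjusted p under 0.01 required of each gene, the direction calls of the stress markers, iron genes and ribosomal proteins were lost (adjusted p = 0.277, 0.560 and 0.642), and with a log2 change of at least 1 so was that of the root hair genes (adjusted p = 0.258). Class III peroxidases had 4 of 68 members higher and 7 lower, and glutathione S-transferases 2 of 41 in each direction. Over-representation among the changed genes passed for 5 lists in one-sided Fisher's exact tests with every member counted as tested. The adjusted p was 5.73e-15 for root hair genes, 1.21e-06 for class III peroxidases, 0.000115 for stress markers, 0.000338 for iron genes and 0.0378 for glutathione S-transferases. Against a background of the 8607 genes listed in any table, 3 of these 5 calls were kept, and those of the iron genes and glutathione S-transferases were lost (adjusted p = 0.0556 and 0.648). This background holds only genes that some comparison listed, so losses against it, here and below, are partly set by construction.

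The second genotype comparison was made on paraquat. Superoxide dismutase, metal reductase and microRNA genes were among 48 changed genes, 24 higher and 24 lower. After TRM4B, the largest rises were those of the orphan gene QQS (3.16 ± 0.54), AT1G34047 (2.46 ± 0.32), the vitamin B6 synthesis gene PDX1.1 (2.33 ± 0.37), the ubiquitin conjugation gene UBC12 (2.24 ± 0.29), SLO1, WRKY25 (1.59 ± 0.11) and the copper/zinc superoxide dismutase gene CSD1 (1.52 ± 0.17, adjusted p = 0.000665) in the authors' deposited table. The largest falls were those of MRD1 (-6.54 ± 0.46), the basic helix-loop-helix gene CITF1 (AT1G71200, -4.69 ± 0.64), the metal reductase gene FRO4 (-4.50 ± 0.31), AT5G46295 (-4.26 ± 0.52) and the microRNA genes MIR857 (-4.03 ± 0.73) and MIR408 (-3.49 ± 0.42) in the authors' deposited table. The lowest adjusted p of a fall belonged to FSD1, an iron superoxide dismutase gene (-2.48 ± 0.16, adjusted p = 1.39e-06), in the authors' deposited table. FRO4 and UBC12 have close tandem copies, FRO5 and UBC11, with which they could share reads. Of the 22 lists, 5 had a changed member, and none passed the direction test. Root hair and photosynthesis genes had 0 members listed. Antioxidant enzymes were over-represented with 2 of 35 members (adjusted p = 0.0231) and class III peroxidases with 2 of 68 (adjusted p = 0.0429) in one-sided Fisher's exact tests, and both calls were lost against the background of listed genes (adjusted p = 0.0980 and 0.180).

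**Figure D2:**
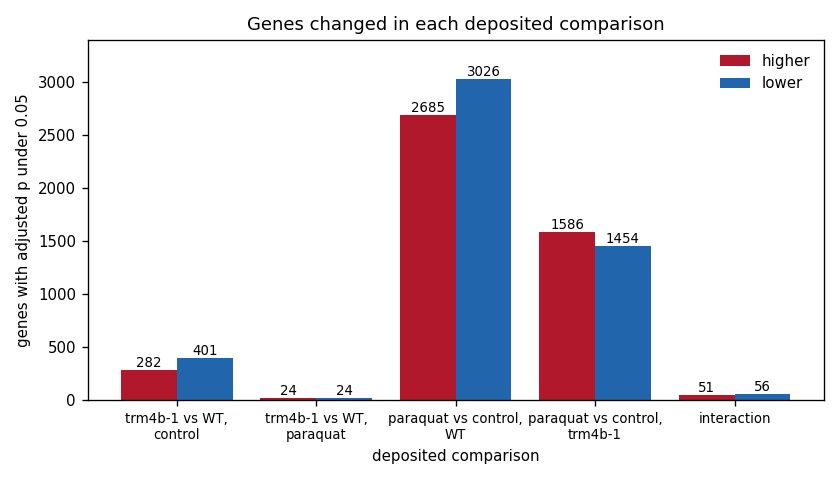
Genes with an adjusted p under 0.05 in each of the 5 deposited comparisons (vertical axis, number of genes), with bars for genes higher (red) and lower (blue). The paraquat comparison of WT had the most, 2685 higher and 3026 lower, and the genotype comparison under paraquat the fewest, 24 and 24.

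Paraquat was then compared with control medium within WT, which asks how wild-type roots respond to the herbicide. Genes that rose included glutathione S-transferases and oxidative and mitochondrial stress markers, and genes that fell included 14 of 15 root hair genes. In all, 5711 genes changed (17.0% of those tested), 2685 higher and 3026 lower. Of 41 glutathione S-transferases, enzymes that conjugate foreign compounds, 16 rose and 4 fell, and at least 23 passed when adjusted over the list alone (direction adjusted p = 0.0139, Fisher's exact test). GSTF3 rose by 4.42 ± 0.43, GSTU12 by 4.08 ± 0.46 and GSTF6 by 3.31 ± 0.15 in the authors' deposited table, though GSTF3 and GSTF6 have close copies that could share reads. Of the 17 stress markers, 11 rose, none fell and at least 12 passed when adjusted over the list alone (direction adjusted p = 0.00135). AT12CYS-2 rose by 5.35 ± 0.34, the alternative oxidase gene AOX1D by 4.74 ± 0.65 and UPOX by 4.65 ± 0.20 in the authors' deposited table. Root hair genes fell in 14 of 15 cases, with none higher and at least 14 past the threshold when adjusted over the list alone (direction adjusted p = 0.00118). PRP3 changed by -2.18 ± 0.22 and LRX1, an extensin of the root hair wall, by -1.71 ± 0.16 in the authors' deposited table. In the same comparison 20 of 26 photosynthesis genes, the markers of shoot tissue, fell.

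The lists in this paragraph did not pass the direction test in WT, and their counts are given whether or not they exceed the share of all genes. Among iron genes 13 of 22 rose and 4 fell (direction adjusted p = 0.0799), with the regulators BHLH100 at 4.27 ± 0.67 and BHLH38 at 2.89 ± 0.27 in the authors' deposited table. Phosphate starvation genes had 8 of 15 higher and 1 lower (adjusted p = 0.0577), sulfate and glutathione supply genes 6 of 9 higher and 1 lower (adjusted p = 0.125), and heat shock genes 7 of 17 higher and 1 lower (adjusted p = 0.0825). SPX3 had 2.41 ± 0.60, the sulfate transporter gene SULTR1;1 -1.74 ± 0.32 and the chaperone gene BIP3 3.40 ± 0.43 in the authors' deposited table. Antioxidant enzymes had 2 of 35 members higher and 8 lower (adjusted p = 0.211), with the ascorbate peroxidase gene TAPX at -1.01 ± 0.28 and the catalase gene CAT3 at -0.91 ± 0.16 in the authors' deposited table. Of the 7 RNA cytosine methyltransferases, 3 rose, NOP2B by 0.87 ± 0.12, NOP2A by 0.58 ± 0.10 and TRM4A by 0.50 ± 0.16 in the authors' deposited table. Counts of members higher and lower were 3 and 8 of 37 for cell cycle genes, 4 and 1 of 22 for genes of the root stem cell niche and polar auxin transport, 3 and 8 of 18 for the endodermal barrier and suberin, and 1 and 1 of 10 for DNA damage. They were 1 and 3 of 20 for jasmonate, 3 and 1 of 16 for abscisic acid, 1 and 1 of 13 for auxin, and 0 and 1 of 9 for cytokinin. Class III peroxidases had 18 and 20 of 68, and the ribosomal proteins 24 and 33 of 329.

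Photosynthesis genes had none higher beside the 20 lower (direction adjusted p = 3.54e-05, Fisher's exact test), and at least 21 passed when adjusted over the list alone. LHCB1.4 had -4.75 ± 1.19 and LHCB1.1 -3.52 ± 1.08 in the authors' deposited table, with standard errors several times the median of 0.147 over changed genes. Of the listed genes of the mitochondrial genome, 45 rose and 2 fell (direction adjusted p = 1.23e-11). The plastid genome had 13 higher and 5 lower (direction adjusted p = 0.0855). Members of a list, above all those of an organelle genome, can move together. The p values of these list tests, in all comparisons, therefore describe the list and do not measure the spread between replicates. Libraries of rRNA-depleted RNA can hold organelle transcripts without poly(A) tails. The largest rises of all were those of AT3G47480 (6.79 ± 0.68), the efflux transporter gene AT2G04050 (6.69 ± 0.47), the cupin gene AT5G38910 (6.53 ± 0.45), the kinase gene WAK3 (6.39 ± 0.70), the glucosyltransferase gene DOGT1 (6.31 ± 0.43) and CYP71A13, a cytochrome P450 of camalexin synthesis (6.15 ± 0.57), in the authors' deposited table. CYP71A13 has a near-identical copy, CYP71A12, that could share reads. The largest falls were those of the glutamate receptor gene GLR2.3 (-6.02 ± 0.45) and AT5G62360 (-4.89 ± 0.44) in the authors' deposited table. Among falls the lowest adjusted p belonged to UMAMIT17, a transporter gene (-3.68 ± 0.15, adjusted p = 3.62e-09), and the clock gene TOC1 (-1.85 ± 0.10, adjusted p = 1.18e-08), in the authors' deposited table. Over-representation passed for 10 of 20 lists against all genes tested, and against the background of listed genes 0 of those 10 calls were kept. Of the 8607 genes in that background 7253 are listed in this comparison itself, so the loss is partly set by construction.

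Within the libraries labelled trm4b-1, paraquat changed 3040 genes (9.05% of those tested), 1586 higher and 1454 lower. Of 15 root hair genes 0 changed, with 2 listed. Of 17 stress markers, 11 rose, none fell and at least 11 passed when adjusted over the list alone (direction adjusted p = 0.00742, Fisher's exact test, lost at 0.135 with a log2 change of at least 1). AOX1D rose by 5.07 ± 0.64, AT12CYS-2 by 3.18 ± 0.22 and the glucosyltransferase gene UGT74E2 by 2.34 ± 0.14 in the authors' deposited table. Of 37 cell cycle and DNA replication genes, 14 fell, 1 rose and at least 17 passed when adjusted over the list alone (direction adjusted p = 0.00336, lost at 0.0700 with an adjusted p under 0.01 per gene). The cyclin genes CYCB1;1 and CYCA2;2 changed by -0.84 ± 0.18 and -0.82 ± 0.16 in the authors' deposited table. In WT 8 genes of this list fell and 3 rose, and 0 of the 37 were listed in the interaction. No difference between the genotypes was thus found for this list. Glutathione S-transferases had 16 of 41 higher and 4 lower (direction adjusted p = 0.0678), with GSTF3 at 5.26 ± 0.46 and GSTU12 at 4.26 ± 0.49 in the authors' deposited table. Photosynthesis genes had 1 of 26 higher and none lower. The mitochondrial genome had 44 genes higher and none lower (direction adjusted p = 5.92e-12).

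The largest rises with paraquat in the libraries labelled trm4b-1 were those of AT5G38910 (8.21 ± 0.51), the senescence gene SAG13 (8.02 ± 0.77), AT1G26390, a berberine bridge enzyme family gene (6.35 ± 0.47), and CYP71A13 (6.34 ± 0.55) in the authors' deposited table. The largest falls were those of AT1G58983 (-7.08 ± 0.55), FRO5 (-6.99 ± 1.15), CITF1 (-4.97 ± 0.63), GLR2.3 (-4.59 ± 0.35) and FRO4 (-4.50 ± 0.31) in the authors' deposited table. The lowest adjusted p of a rise belonged to IGMT2, an indole glucosinolate methyltransferase gene (2.84 ± 0.11, adjusted p = 7.12e-10), in the authors' deposited table. Of falls it belonged to ABF1, a transcription factor gene of abscisic acid signalling (-2.35 ± 0.12, adjusted p = 1.16e-08), and TOC1 (-1.77 ± 0.10, adjusted p = 1.97e-08), in the authors' deposited table. Antioxidant enzymes had 5 of 35 members higher and 5 lower, with FSD1 at -2.53 ± 0.16 and CSD1 at 1.70 ± 0.17 in the authors' deposited table. Iron genes had 8 of 22 higher and 4 lower, phosphate starvation genes 7 of 15 higher and none lower, and abscisic acid genes 5 of 16 higher and 1 lower, and these did not pass the direction test. Over-representation passed for 13 of 20 lists against all genes tested. Against the background of listed genes 4 of those 13 calls were kept, namely the stress markers, glutathione S-transferases, cell cycle genes and iron genes. With an adjusted p under 0.01 required of each gene the call of the cell cycle genes was lost (adjusted p = 0.0936).

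**Figure D3:**
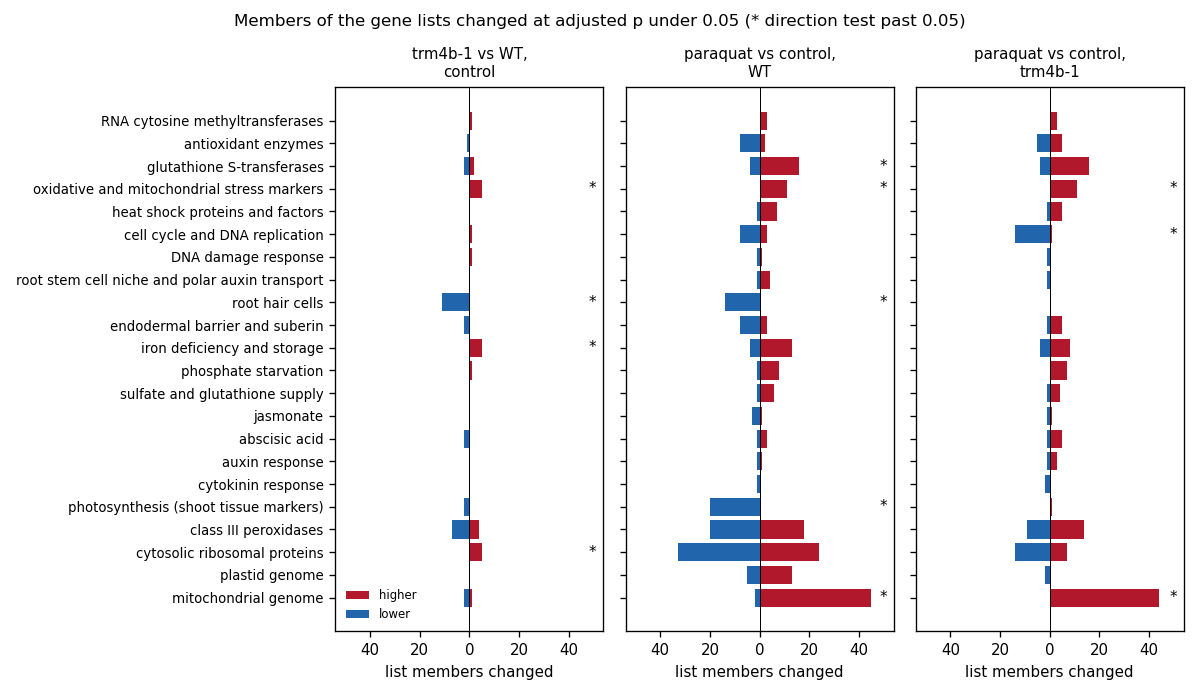
For each gene list, the number of members higher (red, to the right) and lower (blue, to the left) at an adjusted p under 0.05, in 3 of the deposited comparisons. An asterisk marks lists whose direction differed from that of the other changed genes in Fisher's exact test, and root hair genes were lower in 11 cases between the genotypes and in 14 cases with paraquat in WT.

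The paraquat responses of both genotypes were set side by side, using comparisons with no library in common. Of the 5711 and 3040 changed genes, 2203 were shared, against 516.7 for independent lists, and 2190 of the shared genes (99.4%) went the same way. Among genes that rose, 1125 were shared against 126.7 for independent lists (odds ratio 47.6), and among genes that fell 1065 against 130.9 (odds ratio 42.1). With only the 8607 listed genes as background, the odds ratio over both directions fell from 20.3 to 1.54. Of that background 7253 genes are listed in the WT comparison itself and 4087 in the other, so the fall is partly set by construction. AT5G38910, CYP71A13, CYP82C2 and AOX1D had log2 changes of 6.53, 6.15, 5.90 and 4.74 in WT and 8.21, 6.34, 6.24 and 5.07 in the libraries labelled trm4b-1, in the authors' deposited tables. The median ratio of the change in the libraries labelled trm4b-1 to that in WT was 0.932 over the 2190 genes. Genes are not independent replicates, so these counts describe the lists.

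**Figure D4:**
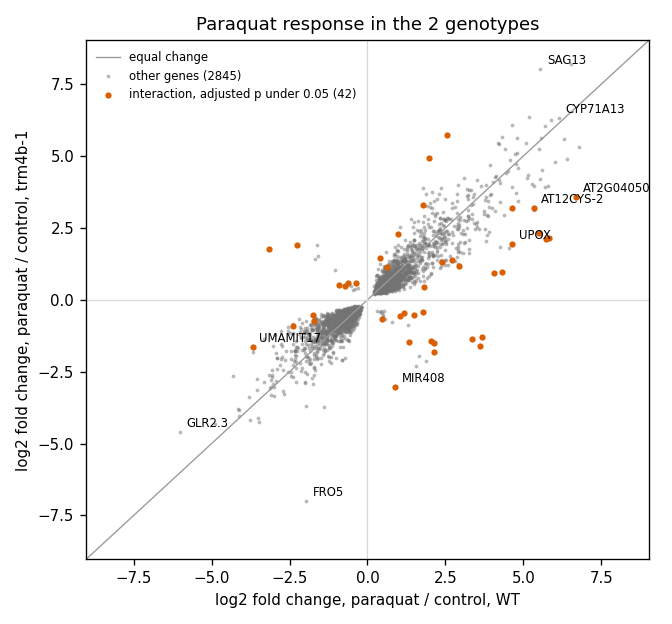
Log2 fold change with paraquat in WT (horizontal) and in libraries labelled trm4b-1 (vertical) for the 2887 genes listed in both deposited tables, 1 point per gene. Orange points are the 42 of them with an interaction at an adjusted p under 0.05, and of the 2203 genes changed in both comparisons 2190 have the same sign on both axes.

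The genotype difference under control conditions was compared with the paraquat response of WT. UPOX, NDB4 and AT12CYS-2 were higher in both, and PRP1, PRP3 and LRX1 lower in both. Of the 683 genes changed between the genotypes, 550 (80.5%) also changed with paraquat in WT, and 529 of these (96.2%) went the same way. Were the genotype labels exchanged in both conditions, this would instead be a difference of the mutant controls from WT opposite to the mutant's own paraquat response. Independent lists would share 116.1. Among genes higher, 209 were shared against 22.5 for independent lists (Fisher's exact p = 4.45e-167), and among genes lower 320 against 36.1 (Fisher's exact p = 7.06e-259), 2 of them members of the photosynthesis list. PRK, a photosynthesis gene outside that list, was lower in both as well (-2.36 ± 0.51 and -3.31 ± 0.56 in the authors' deposited tables). With only the listed genes as background, the odds ratio over both directions fell from 22.2 to 2.21. Of that background 7253 genes are listed in the WT paraquat comparison itself, so this fall is also partly set by construction. Both comparisons use the same 3 WT control libraries, which cannot be split without values per sample, so part of the sharing may come from them. With unchanged groups simulated against shared controls, the lists shared a mean of 9.6 genes and at most 18 in 100 simulations, and 100% of those went the same way. Genes were simulated as independent, so these numbers are no bound for a state of the control libraries that moves many genes together. Paraquat in the libraries labelled trm4b-1, which uses no WT library, shared 211 of the 683 genes, and 130 of those (61.6%) went the same way. It does share the control libraries labelled trm4b-1, with the opposite sign, so noise in them pulls towards opposite directions. Unchanged groups simulated for this pair shared a mean of 7.33 genes and at most 15, and 0% of those went the same way. Over the 597 genes with a listed or rebuilt value in both, the rank correlation was -0.00154 (Spearman) and the linear correlation -0.137 (Pearson).

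**Figure D5:**
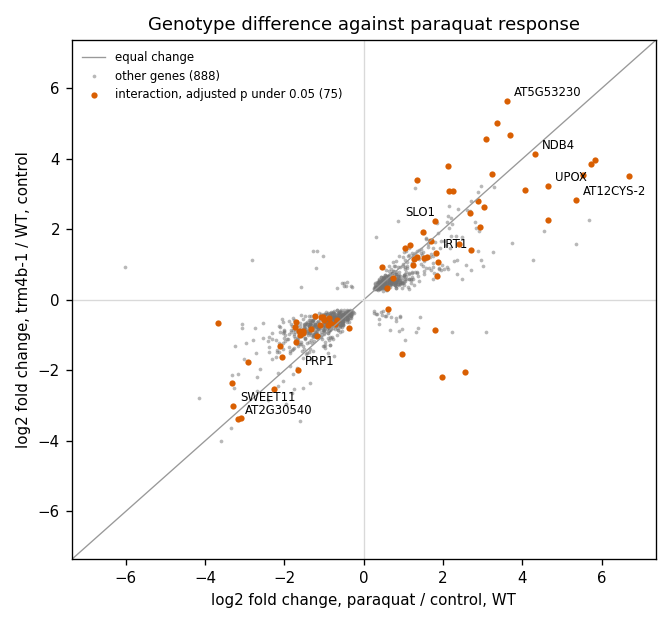
Log2 fold change with paraquat in WT (horizontal) and of libraries labelled trm4b-1 over WT on control medium (vertical) for the 963 genes listed in both deposited tables, 1 point per gene. Orange points are the 75 of them with an interaction at an adjusted p under 0.05, and of the 550 genes changed in both comparisons 529 have the same sign on both axes, although the WT control libraries are part of both.

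The interaction asked whether the paraquat response differs between the genotypes, and 107 genes changed by this test, 51 with a more positive response in the libraries labelled trm4b-1 and 56 with a more negative one. Stress markers, iron uptake genes and root hair genes were among them. The interaction was -3.37 ± 0.39 for NDB4, -2.72 ± 0.23 for UPOX (adjusted p = 4.04e-05) and -2.17 ± 0.41 for AT12CYS-2 in the authors' deposited table. UPOX rose by 4.65 in WT and by 1.93 in the libraries labelled trm4b-1, in the authors' deposited tables. It was already 3.23 higher in those libraries than in WT on control medium, and 0.51 higher on paraquat, in the authors' deposited tables. FRO2 had -1.60 ± 0.22, IRT1 -1.39 ± 0.20 and CYP82C4 -1.29 ± 0.26 in the authors' deposited table. Of 15 root hair genes, 4 had a positive interaction and at least 8 passed when adjusted over the list alone, with 2.25 ± 0.38 for PRP1 and 1.31 ± 0.18 for RSL2, a root hair transcription factor, in the authors' deposited table. The superoxide dismutase genes went apart, FSD1 with -2.69 ± 0.22 and CSD1 with 2.05 ± 0.24, in the authors' deposited table. The most negative interactions were those of AT1G58983 (-7.22 ± 0.94), CITF1 (-5.62 ± 0.72) and AT5G53230 (-5.24 ± 0.60) in the authors' deposited table. The most positive were those of AT2G30540, a thioredoxin family gene (4.94 ± 0.81), AT1G24485 (4.56 ± 0.86) and the phosphoribulokinase gene PRK (4.37 ± 0.81), in the authors' deposited table. AT1G24485 may lie at a floor in the WT paraquat and trm4b-1 control groups, so its value is uncertain.

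Of the 107 interaction genes, 72 had a smaller absolute paraquat change in the libraries labelled trm4b-1 than in WT (67.3%), and in 58 the values had opposite signs, with values that were rebuilt or not past the threshold counted too. In both paraquat comparisons 34 of the interaction genes changed, 13 of them in opposite directions. The interaction genes included 78 that differed between the genotypes under control conditions and 22 that differed under paraquat. Of the 78, 1 had an interaction in the direction of its genotype difference, and of the 22, 20 did. These counts share libraries with the interaction itself and are descriptive. The WT control libraries are among those shared, so a state of them may contribute to the interactions of the 78. None of the lists passed the direction test. Over-representation passed for 4 of 20 lists, with adjusted p = 2.58e-06 for root hair genes, 0.000207 for stress markers, 0.000308 for iron genes and 0.0279 for antioxidant enzymes (one-sided Fisher's exact tests). Against the background of listed genes 3 of the 4 calls were kept, and that of the antioxidant enzymes was lost (adjusted p = 0.114). With an adjusted p under 0.01 required of each gene the call of the root hair genes was lost (adjusted p = 0.0502). Photosynthesis genes had 4 of 26 listed and 0 changed in the interaction, and at least 4 passed when adjusted over the list alone, while PRK, which is outside the list, changed.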

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

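Of the tests of explanations in this part, those of the long linked segment and the first forms of the tests of noise and of a state of the control libraries were written before their results were seen, and all others after. Both of these first forms were replaced once their results were known. The first test of noise took the genes that go the same way in both comparisons, of which 153 of 172 listed with paraquat in the libraries labelled trm4b-1 went the same way there (89.0%). The first test of a control state found 129 of those 529 genes (24.4%) called the same way there, above the 5% that had been set in advance as counting against such a state, and a listed or rebuilt value for only 37.3% of the genes not called there. Neither is used here, because the genes had been picked for going with the WT response, and a gene that responds to paraquat in both genotypes passes such a test whatever the state of the WT controls. The replacements were written with the values partly known, so they carry less weight than tests planned in advance. The bounds of the copper tests and of the test for shoot tissue in the higher genes were reworded after their values were known, and the test of copper supply replaced one on the median change in WT (0.13 over 12 genes), in which 9 of the WT values were rebuilt. The long linked segment was first set in megabases and then in genes, before its result was seen.

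The difference of the paraquat response between the genotypes, tested as the interaction, picked out 107 genes for a closer look. Log2 interactions in the authors' deposited table above 0 were 4.94 for AT2G30540, 4.56 for AT1G24485, 4.37 for PRK, 4.16 for AT4G37483, 3.94 for QQS, 3.52 for SWEET11, 3.17 for AT3G21352 and 2.96 for AT1G52820. They were 2.25 for PRP1, 2.05 for CSD1, 2.04 for UMAMIT17, 1.31 for RSL2, 1.27 for LRX1, 1.19 for RHS12 and 1.01 for TRM4B in the authors' deposited table. AT1G24485 and AT4G37483 may lie at a floor in the WT paraquat and trm4b-1 control groups, so their values are uncertain. Interactions below 0 in the authors' deposited table were -7.22 for AT1G58983, -5.62 for CITF1, -5.24 for AT5G53230, -4.98 for AT4G05380, -4.71 for AT4G05370, -4.20 for NAC085, -4.15 for FRO4, -3.93 for AT5G54560, -3.92 for MIR408 and -3.67 for AT5G52940. Smaller ones in the authors' deposited table were -3.37 for PRX52, -3.37 for NDB4, -3.12 for AT2G04050, -2.72 for UPOX, -2.69 for FSD1, -2.23 for ACC2, -2.17 for AT12CYS-2, -1.60 for FRO2, -1.39 for IRT1 and -1.29 for CYP82C4.

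Genes that differ between the genotypes under control conditions mostly move the same way as WT does with paraquat, and the WT control libraries are part of both comparisons. Sampling noise of those controls as the whole cause was tested on 256 genes. These changed between the genotypes and were listed with paraquat in the libraries labelled trm4b-1. Of them, 154 went the same way there (60.2%, exact 95% interval 53.9 to 66.2). More thus went the same way than the opposite way, which argues only against noise that is independent between genes as the whole cause. However, 153 of the 154 are also among the 172 genes of the first test, which had been picked for going with the WT response. Genes are not independent either, so noise that moves many genes together is not tested. With rebuilt values included, the correlations of that comparison were -0.00154 (Spearman) and -0.137 (Pearson). Both sides of that comparison use the control libraries labelled trm4b-1, with opposite signs. Noise in those libraries lowers the share and the correlations, and unchanged groups simulated for this pair gave 0% in the same direction. A state of the WT controls alone is argued against for 6 genes called the same way between the genotypes on paraquat, where independent lists would give 0.378. They include SLO1, the neighbour of TRM4B, whose rise may have a local cause at that locus and then says nothing about other genes. For the genes other than these 6, such a state cannot be told apart from an effect of the genotype. Only 53.3% of them have a listed or rebuilt value between the genotypes on paraquat. Shoot tissue in the WT control roots cannot be told apart for the 209 shared higher genes as a set. Their median of 0.82 (bootstrap 95% interval 0.72 to 0.95) stays below a limit of 1 for dilution by shoot RNA, worded after the values were known. The limit was applied to the median alone, and single genes, NDB4 and UPOX among them, rose by more than it. Moreover, 11 root hair genes fell where dilution would raise them. Nor can shoot tissue be told apart for the 320 lower ones, which include 2 members of the photosynthesis list and, outside it, PRK. An effect of the genotype that resembles mild paraquat stress may also account for the pattern and is untested, and were the genotype labels exchanged in both conditions, the mutant controls would differ from WT opposite to the mutant's own paraquat response.

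TRM4B RNA is higher, not lower, in the libraries labelled trm4b-1. An exchange of genotype labels in only 1 growth condition is argued against by rises in both, the smaller being 2.89, while an exchange in both conditions cannot be told apart, since it would turn all genotype differences alike, the 3.90 on paraquat to a fall, and no value in the tables excludes it. A long linked segment from another strain is argued against by the 500 annotated genes around TRM4B, of which 16 were listed under control conditions against 1203 of 37398 others (odds ratio 0.995, exact 95% interval 0.562 to 1.64, with annotated genes that were not tested counted as not listed), while a short one cannot be told apart, since 2 of the 20 genes within 10 of TRM4B were listed there, SLO1 and CYP79B3 (-0.48 ± 0.12 in the authors' deposited table), too few to decide. Transcription started by an insertion at the locus remains a candidate explanation, as 1 immediate neighbour, SLO1, was higher in both genotype comparisons, but that rise was known when the test was written. No biological explanation was tested.

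Genes that rise in copper deficiency are lower with paraquat in the libraries labelled trm4b-1, by a list of 15 genes written after its leading members had been seen, so that its counts and intervals are biased by that choice. On paraquat 10 were lower than in WT and none higher, with COPT2 and ZIP2, named here after their values were seen, at -2.75 ± 0.28 and -1.21 ± 0.10 in the authors' deposited table, and under control conditions 0 were listed. Against control medium, paraquat lowered 11 and raised 1 in the libraries labelled trm4b-1. In WT it lowered 1 and raised 3, so part of the genotype difference may come from rises in WT. A change of copper supply in all paraquat medium that acts alike in both genotypes is argued against, as the whole cause, by 9 of the 15 genes with a lower response in the libraries labelled trm4b-1 at an adjusted p under 0.05 over all tested genes. A separate plate or harvest batch of the paraquat roots labelled trm4b-1 cannot be told apart from an effect of paraquat in that genotype. The median interaction of -2.41 over 12 genes, rebuilt values included (bootstrap 95% interval -4.03 to -0.86), sits mostly in that 1 group of libraries. Either such a batch or such an effect may be the cause, and the labels give no batches.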

How the results depend on the processing

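The comparisons with an adjusted p under 0.1, with Storey q values and with the other paraquat table were chosen after the data were seen, and the other alternatives before. Changed genes numbered, for the genotypes under control conditions, the genotypes on paraquat, paraquat in WT, paraquat in the libraries labelled trm4b-1 and the interaction, 161, 26, 3450, 1730 and 34 with an adjusted p under 0.01, and 41, 19, 648, 449 and 23 with Holm adjustment. A log2 change of at least 1 left 218 genes for the genotypes under control conditions and 1858 and 1071 for the paraquat comparisons of WT and of the libraries labelled trm4b-1. With an adjusted p under 0.1 there were 1225, 75 and 317 genes for both genotype comparisons and the interaction, and by the Storey q the interaction had 229. The overlap of both paraquat responses held 1243 genes with an adjusted p under 0.01 and 686 with a log2 change of at least 1. That of the genotype difference under control conditions with the WT response held 123 and 156 genes, and 211 with paraquat in the libraries labelled trm4b-1 in its place. Of 34 over-representation calls, 10 were kept against the background of listed genes, and 24 with an adjusted p under 0.01 per gene. Of 12 direction calls, 8 were kept with an adjusted p under 0.01 and 6 with a log2 change of at least 1. These settings differ in how many genes they let pass by construction.

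Other counts stayed within 1.5 times, among them those without organelle genes. The interaction rebuilt from the paraquat contrasts called 130 of 2887 genes listed in both, and all 42 deposited interaction genes among these were in it. TRM4B kept its values when rebuilt from the other contrasts. Neither result is an independent check, since the deposited contrasts add up to each other and the rebuilt values use the same estimates. Of 267 results for named genes, 64 missed an adjusted p under 0.01, 43 a log2 change of at least 1 and 138 Holm adjustment, and none turned direction, since fold changes are the same in these settings.

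No paired analysis was possible because the deposited tables hold no values per sample. For the same reason a replicate block, leaving out each replicate, other normalizations and tests, other filters, tests of genes with low expression and other splits of the samples were planned or required but not run. Depth is unknown, so it cannot be said in general which genes were too low to test.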

Other observations

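The gene lists in this part, and both tests on the clock, were chosen after their leading genes had been seen, so they are hypotheses found and tested on the same data. The genes named from them were picked with their values known. Clock genes moved with paraquat in both genotypes. Of 12 clock genes expressed in the evening, 12 were lower in WT and 12 in the libraries labelled trm4b-1, with medians of -2.08 and -2.04. FKF1 changed by -3.77 ± 0.23 and -4.17 ± 0.29, ELF4 by -3.54 ± 0.23 and -3.12 ± 0.22 and PRR5 by -1.65 ± 0.12 and -1.93 ± 0.13 in the authors' deposited tables. Of 9 morning genes, 6 were higher and 1 lower in each genotype, with medians of 1.49 and 2.00 over the 7 listed, and the core clock gene CCA1 had 2.16 ± 0.18 and 2.98 ± 0.21 in the authors' deposited tables. In the genotype comparisons 0 of the 21 genes were listed.

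Genes of salicylate and camalexin defence were higher with paraquat in 7 of 16 cases in WT and 6 in the libraries labelled trm4b-1, with none lower. CBP60G, a regulator of salicylate synthesis, had 4.79 ± 0.46 and 5.10 ± 0.49, and FMO1 2.90 ± 0.27 and 2.81 ± 0.29 in the authors' deposited tables. PAD3, the last enzyme gene of camalexin synthesis, had an interaction of -1.47 ± 0.24 in the authors' deposited table. Of 5 genes for copper proteins targeted by copper microRNAs, 3 were higher on paraquat in the libraries labelled trm4b-1 than in WT, CSD1 by 1.52 ± 0.17, ARPN by 1.06 ± 0.14 and CCS by 0.92 ± 0.14 in the authors' deposited table.

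A candidate explanation of the clock genes is a different phase of the clock in the paraquat roots. Leaving out the 5 evening genes first noticed, 7 of 7 evening genes were lower against 1 of 7 changed morning genes, with a two-sided Fisher's exact p of 0.00466 in each genotype. No morning gene was left out, and clock genes are not independent of each other, so this p is descriptive. The wording of this test was changed 2 times after all of the values were known. A different hour of harvest of the paraquat roots would give the same values, and it cannot be told apart, as the labels give no hour and 0 of the 21 clock genes changed in the interaction. That test was run, dropped and later put back.

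Among 47 genes changed between the genotypes on paraquat that could be placed on the chromosomes, 3 pairs were immediate neighbours, namely TRM4B and SLO1, APD3 and PDX1.1, and UBC11 and UBC12. On paraquat APD3 had -3.29 ± 0.55 and PDX1.1 2.33 ± 0.37, and UBC11 -0.65 ± 0.11 and UBC12 2.24 ± 0.29, in the authors' deposited table. Whether this exceeds chance was not tested, and a permutation test written for it was dropped before it was run.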
